A study of Rangifer tarandus with 4 samples.

How the data were processed

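Cells from 4 blood samples of reindeer were profiled as single-cell 3′ RNA libraries, 2 from the saphenous vein (back) and 2 from the distal antler velvet. Groups were taken from the tissue given in the labels. STAR, Cell Ranger 3 and Seurat are named in the submitters' processing notes, without the step each was used for. Cell-by-gene counts were not used here, so the planned test of antler against back was not run and the depth of each library is not given.

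The file used was the gene annotation deposited for the series, 1 table in gene transfer format with 1020224 feature lines. Per the file headers it describes the cattle assembly ARS-UCD1.2. How the authors applied this annotation to reindeer reads is not given in the sources used here. Its values are start and end positions in bases, counted from 1 and belonging to no sample. Per the file, the biotypes were protein-coding genes and immunoglobulin and T cell receptor segments, and it held genes of no other biotype. Genes lay on 31 assembled sequences and 97 unplaced scaffolds. No genome sequence was used, and no reindeer coordinates are given.

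From the features, each gene was given its longest 3′ UTR over its transcripts (the sum of its annotated 3′ UTR segments, without the stop codon), the largest number of exon bases shared with 1 other gene on the same strand, and the distance from its 3′ end to the next gene on its strand. A gene had a 3′ UTR if at least 1 base was annotated and shared exons if at least 1 base was shared. A gene was called named if it carried a symbol that was not an identifier. Genes were looked up by exact symbol, with a few alternative symbols fixed in advance, so a gene listed under another symbol counts as not matched. Of 426 entries in the 27 lists, 393 were matched; a gene in more than 1 list is counted in each, and 1 symbol can match more than 1 gene.

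The lists were 11 sets of blood cell markers, 3 sets of markers of other cells (endothelial cells, fibroblasts, keratinocytes) and 13 functional groups. Lists, the tests reported under Results and their alternatives were fixed before the data were examined, except where the text says otherwise. Blood cell markers were compared with all other named protein-coding genes, and each list with all named genes outside it. Shares were compared by two-sided Fisher's exact tests with Benjamini-Hochberg adjustment over the 27 lists, and medians by two-sided permutation tests with 100000 resamples, whose smallest p is 1e-05. Intervals are 95% exact (Clopper-Pearson) intervals; they treat genes as independent, and cover counting error only. The genes named were, per list, the first matched member with its coordinates, every member not matched, every member without a 3′ UTR, every member with shared exon bases, and the members with the longest and the shortest 3′ UTR; some genes that this rule takes are not reported here. The S100 genes, ELANE, GZMB and the genes named beside the alternative transcript choice were named after their values were seen. A planned test of alignment identity of transferred gene models was not run because the annotation carries no such attribute.

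The reader of the annotation was tested on a simulated annotation of 2000 genes, where the 3′ UTR length and the shared bases came out exactly for 2000 genes and the downstream distance for all 1998 genes with a neighbour. In 100 simulated lists without a difference, Fisher's exact test and the permutation test each passed 0.05 in 4. With medians cut to 60 percent the permutation test passed in 100, and with a share of 65 against 80 percent Fisher's exact test passed in 100. The simulation drew lengths evenly over a range and genes independently, with fewer resamples in the permutation test. Each simulated gene had a single transcript and an unbroken 3′ UTR. The choice of the longest 3′ UTR over transcripts and the summing of its segments were therefore not tested. Its differences were larger than those found for the blood cell markers, so it does not show the power of the tests on these data. Work was done in Python 3.11.15 with NumPy 2.4.6, pandas 2.3.3 and SciPy 1.17.1, and figures were drawn with matplotlib 3.10.9. Alternatives changed the minimum length, the transcript read, the background, the strand, the partner and the chromosomes used, and left out each blood cell list in turn.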

Results

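Single-cell RNA libraries were prepared from peripheral blood mononuclear cells of reindeer (Rangifer tarandus) on day 3 after a wound. Venous blood was drawn at 2 sites, the saphenous vein (back) and the distal antler velvet (antler), with 2 libraries per site, and about 12000 cells were loaded for each library. The titles carry 2 codes, each found in 1 library of either site; the labels do not say what a code marks. The design sets blood cells from the supply of the antler velvet against blood cells from the supply of back skin. The cell-by-gene counts of the 4 libraries were not analysed here, so no expression level, cell share, depth or difference between antler and back is given. The material used was the gene annotation deposited for the series, a list of gene models of cattle (Bos taurus) on the assembly ARS-UCD1.2. All coordinates below are on that assembly and count from 1. The libraries were read at the 3′ end of transcripts, so the questions asked of the annotation were which blood cell genes it holds, whether their models extend past the stop codon into a 3′ untranslated region (UTR), and whether they share exon bases with a neighbour.

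The annotation held 21880 genes with 37538 transcripts. Of these genes, 21861 were protein-coding, and 16808 of the protein-coding genes carried a symbol. A 3′ UTR was annotated for 14319 protein-coding genes, or 65.5%, with a median length of 626 bases among genes that had one (quartiles 270 and 1143 bases). Genes with a symbol had a 3′ UTR in 79.8% of cases (13409 of 16808), and genes without a symbol in 18.01% (910 of 5053). The difference of 61.8 percentage points gave a p below the smallest number that double precision holds (two-sided Fisher's exact test). These are counts over gene models, which are not independent replicates, because members of a gene family can lie side by side and resemble each other.

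Marker genes of blood cells were annotated with a 3′ UTR slightly more often than other named genes in the main test, with a p close to the threshold, and the median of those 3′ UTRs was lower. Most alternatives tried for the share ended its call or turned its direction, and 6 of 14 tried for the length ended its call. The lists cover blood cells in general, granulocytes, red cells and platelets included, while the libraries were of mononuclear cells. Which of the listed cells the libraries held was not examined, so these results concern the lists and not the cells profiled. The 11 blood cell lists matched 147 genes, and 127 of them had a 3′ UTR, or 86.4% (95% exact interval 79.8% to 91.5%), against 79.7% of 16661 other named protein-coding genes. The difference of 6.68 percentage points had p = 0.0494 in a two-sided Fisher's exact test. Against all other protein-coding genes, of which 65.4% had a 3′ UTR, it was 21.04 percentage points; that background adds the unnamed genes, which lists matched by symbol cannot hold, so this value carries the gap between named and unnamed genes. The call ended when any 1 of 8 of the 11 lists was left out or when at least 50 bases were required (6.71 percentage points, p = 0.0580, Fisher's exact test). Without B cells or dendritic cells it ended although the difference, 6.75 percentage points, was no smaller. The direction turned when a 3′ UTR had to be at least 200 bases long, at which 63.9% of marker genes and 66.2% of other genes qualified (p = 0.599, Fisher's exact test). The median 3′ UTR of marker genes that had one was 475 bases, against 651 bases in the other named genes (difference −176 bases, two-sided permutation test, p = 0.0274, 127 against 13282 genes). Each list was also left out in turn, which was chosen after the data were seen. The call ended without neutrophils (−88 bases, p = 0.307, permutation test), red cells (−117.5 bases, p = 0.163, permutation test) or dendritic cells (−139 bases, p = 0.0896, permutation test). It also ended with 1 transcript per gene (−141.5 bases), against all other protein-coding genes (−151 bases) and with genes lacking a 3′ UTR set to 0 bases (−38 bases, p = 0.602, permutation test). Across all 27 lists, the mitochondrial genes were the only list whose share of genes with a 3′ UTR differed from the other named genes after Benjamini-Hochberg adjustment (Fisher's exact test, adjusted p = 2.51e-08). That list is the whole set of mitochondrial genes in the annotation and not a sample, so its p measures no sampling. Before adjustment, 4 lists had a p under 0.05 (Fisher's exact test).

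**Figure D1:**
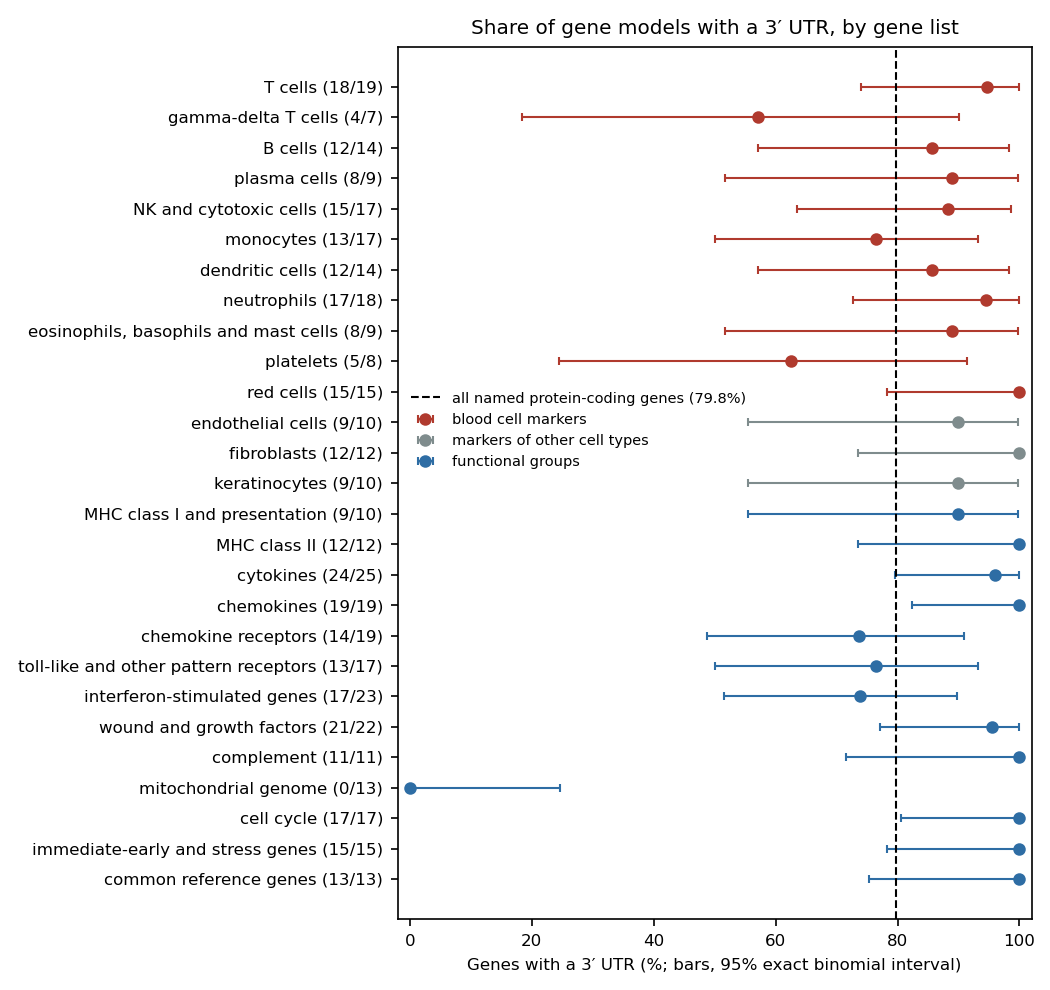
Percentage of matched genes with an annotated 3′ UTR (x axis) for each of the 27 gene lists (y axis, with the counts), with 95% exact binomial intervals and a dashed line at the 79.8% of all named protein-coding genes. The mitochondrial genes stand at 0 of 13, while chemokines (19 of 19) and red cell genes (15 of 15) are complete.

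Among lymphocyte genes, 18 of 19 T cell genes and 4 of 7 gamma-delta T cell genes had a 3′ UTR. All 19 T cell genes were matched, with a median of 974.5 bases. CD3E, a chain of the T cell receptor complex (ENSBTAG00000015710), lay on chromosome 15 from 29004371 to 29015210 on the plus strand, with 3 transcripts and a 3′ UTR of up to 1663 bases. CD3G, another chain of that complex on the same chromosome, had none. The longest 3′ UTR of the list belonged to IL7R, the interleukin 7 receptor, with 2004 bases, and the shortest to CD28, a costimulatory receptor, with 118 bases. Of 16 gamma-delta T cell genes, 7 were matched and 4 had a 3′ UTR. The scavenger receptors of ruminant gamma-delta T cells had little or no 3′ UTR: CD163L1 (ENSBTAG00000054245, chromosome 5, 103022590 to 103086215, minus strand) and WC1.3 had no 3′ UTR, and that of WC1 measured 5 bases. SOX13, a transcription factor of this lineage, had none either. The symbols WC1.1, WC1-8, TRDC and TRGC1 to TRGC6 were not matched and are not analysed here.

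B cell, plasma cell and cytotoxic cell genes were all matched. Of 14 B cell genes, 12 had a 3′ UTR; CD79A, a chain of the B cell receptor complex (ENSBTAG00000001882, chromosome 18, 51344675 to 51348682, minus strand), had the longest with 1461 bases and FCRLA the shortest with 63 bases. The transcription factors PAX5 and EBF1, which set B cell identity, had none. Of 9 plasma cell genes, 8 had a 3′ UTR, among them JCHAIN, the joining chain of secreted antibodies (ENSBTAG00000018531, chromosome 6, 86033000 to 86042396, minus strand), with 696 bases. IRF4 had 3252 bases and DERL3 had 118 bases. XBP1, the transcription factor of the secretory programme, had none. MZB1 shared 212 exon bases with PROB1 on the same strand, more than its own 3′ UTR of 205 bases. Of 17 genes of NK and cytotoxic cells, 15 had a 3′ UTR. NCR1, an activating receptor of NK cells (ENSBTAG00000045529, chromosome 18, 62512088 to 62516410, minus strand), had 136 bases, CCL5 had the longest with 1410 bases and KLRK1 the shortest with 48 bases; KLRD1 and KLRF1 had none. The symbol GZMB, a granule protease, was carried by 2 genes with 3′ UTRs of 97 and 105 bases.

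Myeloid genes had a 3′ UTR in most cases. Of 17 monocyte genes, 13 had one. CD14, the lipopolysaccharide co-receptor (ENSBTAG00000015032, chromosome 7, 51762895 to 51765768, minus strand), had 1586 bases, CD36 had 2145 bases and CD68 had 201 bases, whereas genes without one included CD163, ITGAM and CCR2. Of 14 dendritic cell genes, 12 had a 3′ UTR: FLT3 (ENSBTAG00000018572, chromosome 12, 31991150 to 32060002, plus strand) had 446 bases, CCR9 had 2028 bases and CLEC10A had 90 bases, and XCR1 and IRF7 had none. Of 18 neutrophil genes, 17 had a 3′ UTR, with a median of 120 bases. The genes S100A8, S100A9 and S100A12 had 85, 93 and 110 bases, and the elastase gene ELANE had 101 bases. CSF3R, the receptor of granulocyte colony-stimulating factor (ENSBTAG00000013334, chromosome 3, 109418279 to 109429587, plus strand), had 662 bases, MPO had the longest with 701 bases and CXCR2 the shortest with 45 bases; MMP8 had none. Of 9 genes of eosinophils, basophils and mast cells, 8 had a 3′ UTR, from 105 bases in one of the 2 genes named PRG3 to 2108 bases in KIT. The eotaxin receptor CCR3 (ENSBTAG00000001338, chromosome 22, 53135114 to 53136190, minus strand) had none. MNDA, IL3RA, CATHL1, FCGR3B, SIGLEC8, EPX and PRG2 were not matched by symbol and are not analysed here.

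**Figure D2:**
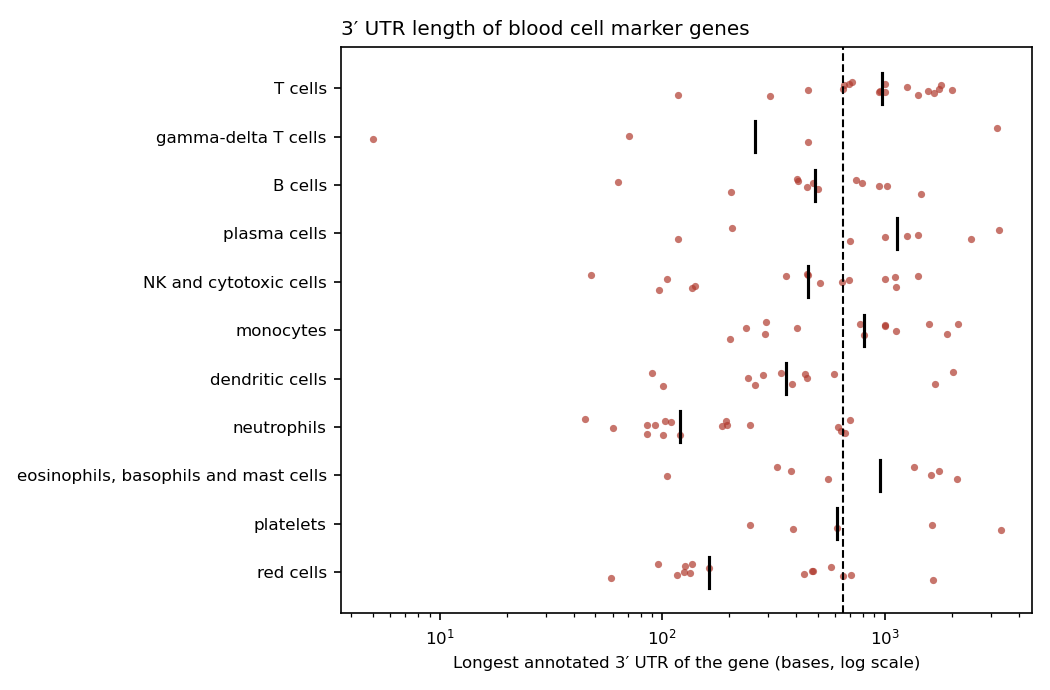
Longest annotated 3′ UTR per gene in bases (x axis, log scale) for the genes of the 11 blood cell lists that have one; each point is a gene, black bars are list medians and the dashed line is the median of the other named genes, 651 bases. The neutrophil genes, with a median of 120 bases, and the red cell genes, with 162 bases, lie mostly left of that line. The medians of the gamma-delta T cell, B cell, NK and cytotoxic cell, dendritic cell and platelet genes also lie left of it. Those of the other lists lie right of it.

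Platelet genes were the blood list with the second lowest share after the gamma-delta T cell list, with 5 of 8 matched genes having a 3′ UTR. The integrin chains ITGA2B (ENSBTAG00000008165, chromosome 19, 44172212 to 44185276, minus strand) and ITGB3 had 248 and 3321 bases, the shortest and the longest of the list. GP9, GP1BA and GP1BB, which encode parts of the receptor for von Willebrand factor, had none. GP1BB also shared 608 exon bases on the same strand with SEPT5, beside a coding length of 660 bases. The chemokine symbols PPBP and PF4 were not matched and are not analysed here. All 15 matched red cell genes had a 3′ UTR, with a median of 162 bases. HBB, the beta chain of haemoglobin (ENSBTAG00000037644, chromosome 15, 48362236 to 48363996, plus strand), had 125 bases, and SLC4A1, the anion exchanger of the red cell membrane, had 1656 bases. HBM, a globin gene, had the shortest with 59 bases and shared 116 exon bases with the unnamed gene ENSBTAG00000034024. HBZ was not matched.

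Shared exon bases were rare among blood cell genes. Of the 147 marker genes, 3 (MZB1, GP1BB and HBM) shared at least 1 exon base with another gene on the same strand, or 2.04% (95% exact interval 0.423% to 5.85%), against 1.81% of the other named genes (p = 0.750, two-sided Fisher's exact test). With either strand counted, the shares were 6.80% and 9.18% (p = 0.389, Fisher's exact test).

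Markers of endothelial cells, fibroblasts and keratinocytes had a 3′ UTR in most cases. Of 10 endothelial genes, 9 had a 3′ UTR, from 126 bases in VWF to 4518 bases in KDR. PECAM1 (ENSBTAG00000012066, chromosome 19, 48541625 to 48619840, minus strand) had none. All 12 fibroblast genes had one, among them the collagen gene COL1A1 (ENSBTAG00000013103, chromosome 19, 36457658 to 36474513, plus strand) with 275 bases, CRABP1 with 227 bases and PDGFRA with 3269 bases. Of 10 keratinocyte genes, 9 had one, among them KRT5 (ENSBTAG00000038384, chromosome 5, 27366774 to 27373266, plus strand) with 378 bases, KRT17 with 136 bases and DSG1 with 4067 bases. LOR had none, and IVL was not matched.

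All 12 matched class II genes had a 3′ UTR, with a median of 607.5 bases. BOLA-DRA, the class II alpha chain (ENSBTAG00000010645, chromosome 23, 25837353 to 25843155, minus strand), had 1460 bases, BOLA-DOA had 2095 bases, and CIITA, the transactivator of class II genes, had 31 bases. BOLA-DRB1, BOLA-DRB2, BOLA-DRB3 and BOLA-DQA2 were not matched by symbol. Of 10 class I and peptide-loading genes, 9 had a 3′ UTR. B2M, the light chain of class I molecules (ENSBTAG00000012330, chromosome 10, 103116503 to 103123174, plus strand), had exactly 1000 bases, the longest 3′ UTR of 550 genes. PSMB9 had 52 bases, while NLRC5, the class I transactivator, had none. When only the transcript with the longest coding sequence was read, 5 of these 10 genes kept a 3′ UTR, and BOLA, BOLA-NC1, JSP.1 and TAP1 did not. Genes of other lists also lost theirs, among them HSP90AA1, HSPA8, EEF1A1, SLC4A1, ITGA2B, VWF, CXCR2, CD28 and WC1. The lengths reported for those genes belong to other transcripts. Of the 147 blood cell marker genes, 117 kept a 3′ UTR in that reading, against 127 over all transcripts. Similarity between members of the class I and class II families was not tested here.

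A 3′ UTR was annotated for all matched chemokines and 24 of 25 cytokines, and for 14 of 19 chemokine receptors and 17 of 23 interferon-stimulated genes, but none of these lists or the pattern receptors differed from the other named genes after adjustment (Fisher's exact test, adjusted p from 0.238 to 0.762). All 19 matched chemokines had a 3′ UTR, with a median of 944 bases; CXCL8 (ENSBTAG00000019716, chromosome 6, 88810418 to 88814572, plus strand) had 1105 bases, CXCL9 had 2299 bases and XCL1 had 226 bases, and XCL2 was not matched. Of 25 cytokines, 24 had one. IL1B (ENSBTAG00000001321, chromosome 11, 46543394 to 46552101, minus strand) had 880 bases, CSF1 had 2143 bases, IL4 had 96 bases and IL18 had none. Of 19 chemokine receptors, 14 had one, among them CXCR1 (ENSBTAG00000026753, chromosome 2, 106215131 to 106219158, minus strand) with 619 bases. CCR2, CCR3, CCR8, CCR10 and XCR1 had none. Of 17 pattern receptors, 13 had one. TLR2 (ENSBTAG00000008008, chromosome 17, 3954019 to 3967242, minus strand) had 962 bases, NOD2 had 1914 bases and TLR9 had 47 bases. TLR5, TLR6, CLEC4E and the RNA sensor DDX58 had none, and TLR1 and TLR8 were not matched. Of 23 interferon-stimulated genes, 17 had one. ISG15 (ENSBTAG00000014707, chromosome 16, 51464069 to 51465107, minus strand) had 67 bases and OAS1X had 2422 bases. Genes without one included IRF7, a transcription factor of the interferon response, and IFIT1, OAS2, IFI44 and CMPK2. IRF9 shared 223 exon bases with RNF31 on the same strand, and its longest 3′ UTR measured 266 bases. BST2 was not matched.

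Of 22 wound and growth factor genes, 21 had one, with a median of 826 bases; VEGFA (ENSBTAG00000005339, chromosome 23, 17281915 to 17297193, plus strand) had 1116 bases, FGF2 had 6023 bases and HGF had 164 bases. The mannose receptor gene MRC1, a macrophage marker, had none, and EGF and TIMP1 were not matched. All 11 matched complement genes had one, with a median of 205 bases, from 48 bases in CFB to 1942 bases in C3AR1; C1QA (ENSBTAG00000007153, chromosome 2, 130189849 to 130193588, minus strand) had 205 bases. ITGAX was not matched.

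All 13 mitochondrial protein-coding genes, often used to judge cell quality, were matched, and 0 of 13 had a 3′ UTR (95% exact upper bound 24.7%). The list holds every mitochondrial gene of the annotation, so this bound covers no sampling. Each of the 13 gene models had 1 exon, and ND1 (ENSBTAG00000043558) ran from 3101 to 4056. Of these 13 genes, 5 shared bases with a neighbour on the same strand. ATP8 and ATP6 shared 40 bases, ND4L and ND4 shared 7 bases, and COX3 shared 1 base with ATP6. All 17 cell cycle genes had a 3′ UTR, among them the proliferation marker MKI67 (ENSBTAG00000002444, chromosome 26, 47507654 to 47537887, minus strand) with 1215 bases, RRM2 with 1866 bases and CCNB1 with 117 bases. UBE2C shared 408 exon bases with DNTTIP1. All 15 immediate-early and stress genes had one, among them FOS (ENSBTAG00000004322, chromosome 10, 86488645 to 86492108, plus strand) with 542 bases, HSP90AA1 with 3559 bases and HSPA8 with 228 bases. All 13 matched reference genes had one, with a median of 177 bases, among them ACTB (ENSBTAG00000026199, chromosome 25, 38799230 to 38802646, plus strand) with 617 bases, EEF1A1 with 3262 bases and PPIA with 13 bases. MALAT1, a long non-coding RNA, was not matched, and the annotation used held no genes of that biotype.

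Counted by biotype, the annotation used held 19 antigen receptor segment genes, 16 of T cell receptors and 3 of immunoglobulins, and 0 of 19 had a 3′ UTR. A receptor gene filed as protein-coding would not be in these counts. Of these, 13 lay on chromosome 10, and 2 had a symbol, TRAV24 and TRBV24-1. By biotype there was 1 T cell receptor constant gene (ENSBTAG00000049399, chromosome 4, 82745643 to 82745786, plus strand) and 1 immunoglobulin constant gene (ENSBTAG00000017305, chromosome 17, 71131053 to 71166047, plus strand). The other 17 were variable or joining segments, so the 0 of 19 is mostly a count over segments and not over whole receptor genes.

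The median distance to the next gene on the same strand was 46982.5 bases for 7420 protein-coding genes without a 3′ UTR and 45712 bases for 14265 genes with one (p = 0.431, two-sided permutation test). Among named genes alone, those without a 3′ UTR had a longer distance, 54305 against 45834 bases (p = 3.0e-05, permutation test, 3388 against 13380 genes).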

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

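Of 39 alternatives to the 5 tested results, 21 kept the direction and the side of the threshold. Some of the 21 could hardly have differed, because nearly all genes are protein-coding. Counting only protein-coding partners gave the same 3 of 147 and 301 of 16661 genes with shared exon bases. The 21 also include the 21.04 percentage points given below. The cause of the changes was not tested. Leaving each list out of the length comparison and the mitochondrial genes out of the background were chosen after the data were seen. The higher share of blood cell markers with a 3′ UTR (6.68 percentage points) lost its call with at least 50 bases required (6.71, p = 0.0580, Fisher's exact test) and changed sign with at least 200 bases (−2.29). Against all other protein-coding genes it was 21.04, which says nothing of the markers, because that background adds unnamed genes (910 of 5053 with a 3′ UTR) that the lists cannot hold. It also lost its call without T cells (5.44), B cells (6.75), plasma cells (6.51), NK and cytotoxic cells (6.43), dendritic cells (6.75), neutrophils (5.55), eosinophils, basophils and mast cells (6.51) or red cells (5.13). Without B cells or dendritic cells, and with at least 50 bases, the difference was no smaller than 6.68. A lost call there does not show that the difference depends on those genes. The shorter 3′ UTR of the markers (−176 bases) lost its call when read from the transcript with the longest coding sequence (−141.5), with genes lacking one set to 0 bases (−38), against all other protein-coding genes (−151) and without neutrophils (−88), dendritic cells (−139) or red cells (−117.5); it kept its call without each of the 8 other lists. The difference in shared exon bases, not called, changed sign with either strand counted (−2.38). The downstream distance was called only among named genes (8471 bases longer without a 3′ UTR). All alternatives kept the gap between named and unnamed genes. A minimum of 200 bases lowered the count of genes with a 3′ UTR by over 1.5 times in 5 of 27 lists (gamma-delta T cells from 4 to 2, neutrophils from 17 to 5, red cells from 15 to 7, complement from 11 to 6 and reference genes from 13 to 5), and reading 1 transcript per gene did so in 1 (class I genes, from 9 to 5). No paired analysis was possible because no per-sample values were used; no library depth bears on these counts.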

Other observations

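The tests of exon number and stop codons as causes of the gap between named and unnamed genes, and the length comparisons that leave out a list, were chosen after the data were seen, and the patterns were grouped as given here after their tests had been run. The tests matched on coding length, the test without cathelicidin genes and the test of the 1000-base length were not in the original plan either. They concern patterns found in the data, and only their bounds were written before their values were seen. The bound for the comparison without neutrophils, a p of at least 0.05, was written before its value was seen and was met, but the comparison was read as undecided after the value was seen. The study's groups give no biological explanation for a gene model, so no biological explanation was tested.

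The share of genes with a 3′ UTR was lowest on unplaced scaffolds, chromosome 15, the X chromosome and chromosome 23, apart from the mitochondrial genome; differences between chromosomes were not tested. A 3′ UTR was annotated for 46.5% of 986 protein-coding genes on chromosome 15, which holds the CD3 genes and the beta-globin gene, for 57.9% of 845 genes on the X chromosome, for 61.2% of 708 genes on chromosome 23, and for 22.5% of 218 genes on unplaced scaffolds. Genes without a symbol made up 43.4%, 33.5%, 27.0% and 87.6% of these sets. Among named genes the shares were 76.3%, 78.6%, 78.9% and 63.0%, beside 79.8% over all named genes, and chromosomes 24 (75.4%), 8 (77.3%), 1 (77.4%), 2 (78.0%), 14 (78.1%), 16 (78.3%) and 10 (78.5%) also lay below X and 23.

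A longest 3′ UTR of exactly 1000 bases was carried by 550 genes, or 3.84% of protein-coding genes with a 3′ UTR. Each length within 5 bases of it was carried by 3 to 12 genes, and the next most frequent length, 1 base, by 45. The genes include B2M, CD6, TNFRSF17, KLRB1, FCN1, TYROBP, PDGFRB, IL12B, OSM, LIF, CXCL16, CDK1 and NFKBIA. No 5′ UTR had that length (0 genes). A candidate explanation is that these gene models were given a fixed length past the stop codon. It predicts an unspliced stretch. The test covered all 905 transcripts with a 3′ UTR of that length, from 624 genes, also where another transcript of the gene had a longer one. Of these transcripts, 99.9% had their 3′ UTR in 1 block, against 89.7% (95% exact interval 88.0% to 91.2%) of 1472 transcripts within 100 bases of that length. The lengths of these transcripts may therefore be a setting of the annotation.

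The 3′ UTRs of the neutrophil list were short, with a median of 120 bases in 17 genes. Short coding sequences are argued against as the whole cause in that list, because random lists of the same coding lengths had a median of 548 bases and the list stood at percentile 0 of 10000. The cathelicidin genes alone are argued against more weakly, because the median of the 11 other genes was 185 bases, at percentile 0.625 of matched lists. Those genes still include S100A8, S100A9 and S100A12, which lie close together on chromosome 3, while random lists draw genes independently. The neutrophil median was the lowest of all lists, and the percentiles are not corrected for that. Other lists with low medians were not set against matched lists. For all 127 blood cell markers with a 3′ UTR, the median of 475 bases stood at percentile 2.82 of lists matched on coding length, whose median was 609 bases, so coding length stays open there, close to the bound of 2.5. The neutrophil list alone as the cause stays open too: without it the difference was −88 bases (p = 0.307, permutation test), but a missed threshold does not show that no difference is left, and the call also ended without red cells (−117.5 bases; list median 162 bases) or dendritic cells (−139 bases). Whether the short neutrophil models end where the transcripts end was not tested.

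Unnamed genes had a 3′ UTR far less often than named genes. Gene models with few exons are not the whole cause: at equal exon number the difference was 41.5 percentage points, against 61.8 without matching, so exon number may account for part of it. Gene models without a stop codon are argued against by their number, 216 of 21861 protein-coding genes, which is too few for a gap over 5053 unnamed genes; the difference of 62.5 percentage points among genes with a stop codon adds nothing, since so few genes were left out. The shares of named and unnamed genes with a 3′ UTR were 28.8% and 8.65% with 1 exon, 77.7% and 17.7% with 2 to 3 exons, 84.9% and 33.2% with 4 to 9, and 80.8% and 29.97% with 10 or more.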
